A study of Mus musculus with 6 samples.

How the data were processed

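Thyroid RNA of 6 mice was profiled on a whole-transcript Affymetrix array. Per the labels' protocols, mice of a C57BL/6J background aged 6 to 8 weeks received tamoxifen at 0.05 g/kg intraperitoneally on 5 consecutive days, and thyroid was taken 2 weeks after treatment. RNA came from 1 frozen lobe per animal, was treated with DNase and was used where its integrity number was at least 7. From 250 ng of it biotin-labelled cRNA was made with the GeneChip WT PLUS kit. The sex of the animals is not given in the sources used here. Groups were taken from the sample titles and genotypes, with 3 Foxe1flox/flox/Cre animals, called knockouts here, and 3 Cre controls.

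The authors deposited log2 values per probe set, made with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA ordinarily corrects background, equalises the distribution of the arrays and summarises the probes of a probe set on the log2 scale. Its settings, its version, and the annotation and genome build behind the probe sets are not given in the sources used here. The log2 scale was read from the values, which lie between about 2 and 19.93 with nearly equal quartiles on all arrays. Values are rounded to 2 decimals. Such processing compresses differences near the bottom and top of the scale, and it removes any change shared by most transcripts. No detection calls were used, so a low value cannot be told from background. Scanner files were not used here, and no scan date or batch was given.

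Probe sets were named through the platform's annotation table of 2019 and updated through gene identifiers to the RefSeq gene table of assembly GRCm38.p6. Of 22206 probe sets, 19572 carry 1 symbol, 2634 are unnamed here and 0 carry several. All 19572 matched a RefSeq gene. No coordinates are given, since the build behind the files is not named, and the RefSeq table served only for names and gene order. A list gene was matched by its symbol or, where that is no current symbol in the table, by a synonym held by 1 named gene (4 genes). A gene with several probe sets entered its list through the brightest.

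All probe sets were tested, without further normalization or filtering, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Differences are knockout minus control on the log2 scale. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Gene lists, 34 in number with 461 genes of which 412 were measured, were written before the data were examined, as were the tests, the rule for named genes and the first group of other settings named below. They cover thyroid function, cell types a dissected lobe may hold (C cells, parathyroid, immune, stromal, muscle, airway, squamous, nerve and others), stress and metabolic pathways, and the mast cell list. The 32 lists with at least 3 measured members were tested with camera at its preset inter-gene correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry were run as alternatives. Counts "adjusted over the list alone" use limma's p with Benjamini-Hochberg adjustment within the list.

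The rule for named genes took Foxe1 and all measured members of the thyroid hormone synthesis and thyroid transcription factor lists. It added the 12 largest rises and 12 largest falls past the threshold among probe sets with 1 gene symbol that is not a Gm, Rik or LOC name, with all 3 knockout arrays on one side of all 3 controls. Of every other list it took up to 4 members past the threshold or, where none passed and the list passed its set test, the 3 with the smallest p, given as values. Genes named outside it are said to be so. Pth, Casr, Chga, Alas2, the Y-linked genes, the mast cell genes and the genes of the closing section were chosen after their values were seen.

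The other settings chosen beforehand were renewed quantile normalization, median centring, a variance trend with and without robust fitting, array weights, 2 filters on dim probe sets, named probe sets alone, other thresholds, an ordinary t statistic, the replicate number as a block, the mean of a gene's probe sets in lists, and leaving out each array. The median difference over all probe sets was -0.02 as deposited and 0.02 after median centring. Alternatives added after seeing the data were sex read from Y-linked genes as a covariate, leaving out the 2 arrays without Y-linked signal, and the mean of Pth and Casr as a covariate.

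The limma step was tested on simulated data for the knockout against control comparison, with 22206 probe sets, variances drawn from the distribution fitted to these arrays and 50 probe sets changed at each size. It recovered 18% of changes of 1 log2 unit, 94% of changes of 2, 98% of changes of 3 and 100% of changes of 4, with 14 false calls among 169. With no change simulated it made 0 calls. The way variances were drawn was revised after a first run of this test.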

Results

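Gene expression was measured in mouse thyroid 2 weeks after tamoxifen, in animals in which tamoxifen-activated Cre recombinase deletes a floxed Foxe1 gene and in animals that carry Cre without the floxed gene. Foxe1 is a forkhead transcription factor of the thyroid follicular cell, needed for the gland to form and descend in the embryo. The comparison asks what its loss in the adult gland does to the thyroid's transcripts. Lobes of both groups also held transcripts of airway, muscle, squamous and parathyroid tissue. Differing amounts of such tissue taken with the lobes cannot be told apart here from an effect of the genotype. There were 3 Foxe1flox/flox/Cre mice and 3 Cre controls, with 1 lobe and 1 array per animal. Each array gave log2 values for 22206 probe sets, of which 19572 carry 1 gene symbol. Array medians lay between 5.62 and 5.69, and the correlation between any pair of arrays across probe sets lay between 0.97 and 0.99. The number of arrays, 3 per group, limits the precision of every value given here.

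Foxe1 itself was lower on all 3 knockout arrays. It read 7.60, 7.19 and 7.04 in the controls and 3.33, 2.88 and 3.04 in the knockouts, which is 7.28 ± 0.29 against 3.08 ± 0.23 (SD, n = 3 each). The log2 value fell by 4.19 (SE 0.22, limma adjusted p = 0.000442), an 18.3-fold difference. The knockout readings stood between the 9.1th and 21.1th percentile of their own arrays, close to the level of probe sets with little signal, so the fold may be limited by background. Where its probes lie in relation to the floxed segment is not given in the sources used here. The call held without any single array, with adjusted p between 0.00259 and 0.00546, and was lost with an ordinary t statistic (adjusted p = 0.223), which shares no variance between probe sets.

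Beyond Foxe1, the knockout lobes held more rises than falls. At an adjusted p of 0.05, 75 of the 22206 probe sets differed, 56 higher and 19 lower in the knockout, and 66 of the 75 have a gene symbol. All 75 had the 3 knockout arrays on one side of the 3 controls. Over all probe sets 18.1% did so, where chance gives 10%. Changes among the 75 ran from 1.15 to 5.11 on the log2 scale. An unadjusted p under 0.05 was reached by 2828 probe sets, 1467 higher and 1361 lower, against 1110 that chance alone would give.

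The 12 largest rises by the rule fixed for named genes ran from 2.49 to 5.11 on the log2 scale. Arhgef33 rose from 6.37 ± 0.93 to 11.48 ± 0.96 (SD, n = 3 each, adjusted p = 0.0192). Scg5, a secretory granule protein of neuroendocrine cells, rose by 4.36 (adjusted p = 0.0269), and Napsa, an aspartic protease of lung and kidney epithelium, rose by 3.94 (adjusted p = 0.025). Sgpp2, which dephosphorylates sphingosine 1-phosphate, rose by 3.92, the alcohol dehydrogenase Adh6a by 3.73, the adenosine deaminase gene Ada by 3.39 and Alad, an enzyme of haem synthesis, by 2.60. Ecrg4, which encodes a secreted peptide precursor, rose by 3.65. The receptor of gastrin-releasing peptide, Grpr, rose by 3.61 from 3.08 ± 0.17 in the controls, where it stood between the 8.4th and 17.1th percentile of the arrays, so its difference too may be limited by background. Skint6, of an immunoglobulin-like family expressed in skin and thymus, rose by 2.93, Dkkl1 by 2.88 and the potassium channel Kcnk1 by 2.49. The highest adjusted p among these 12 was 0.0445. Control 3 was the lowest control for several of them, such as Scg5, Napsa and Kcnk1, as for several thyroid genes below. Ada, Sgpp2 and Dkkl1 were lowest in control 1 and highest in knockout 3, as was Sprr1b, a gene of the cornified envelope. These likenesses were picked after the values were seen. Differing tissue in the lobes was not separated from the genotype for these rises.

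The 12 largest falls by the same rule, which leaves out Gm, Rik and LOC names, began with Foxe1, and the other 11 ran from -3.21 to -1.49. Krt76, a keratin of oral-type epithelium, fell by 3.21 (8.57 ± 1.06 to 5.36 ± 0.20, SD, n = 3 each, adjusted p = 0.0324), and the cell-surface mucin Muc1 fell by 2.17 (adjusted p = 0.025). The aldehyde oxidase Aox4 fell by 2.43, the steroid dehydrogenase Akr1c18 by 1.85, the R-spondin receptor Lgr6 by 1.80 and the GABA receptor subunit Gabrp by 1.75. Cyfip2, a regulator of actin assembly, fell by 1.87. Enpp3, an ectoenzyme that cleaves nucleotides, fell by 1.73, and Selenbp1 fell by 1.69. Ifitm1, an interferon-induced membrane protein gene, fell by 1.57, and the lipoxygenase gene Alox15 fell by 1.49. The highest adjusted p among the 12 falls was 0.0405.

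These calls depended on every array. Without 1 control the count was 43 (control 1), 9 (control 2) or 16 (control 3), and without 1 knockout it was 2 (knockout 1), 15 (knockout 2) or 4 (knockout 3). Foxe1 and Alad were called in all 6 of these fits, and 34 of the 75 in none. Leaving out 1 array moved the difference of 0 of the 25 genes named here past the threshold by over 1.5 times, and of 21 of the 51 named genes that did not pass. Nearly all of the 25 were picked for large, separated differences on these same arrays. Small differences, such as that of Tg, move by that much easily. The contrast therefore does not measure stability.

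Genes of thyroid hormone synthesis had higher mean values in the knockout, but no single member passed the threshold over all probe sets. Of 12 measured members of the list, 11 had positive differences, and 4 passed when adjusted over the list alone. These were Slc5a5, the sodium iodide symporter, Iyd, the iodotyrosine deiodinase that recycles iodide, Tshr, the thyrotropin receptor, and Duox1, a dual oxidase. Slc5a5 read 8.00, 8.00 and 2.97 in the controls and 11.50, 10.34 and 11.61 in the knockouts, a difference of 4.83 (SE 1.18, adjusted p = 0.14 over all probe sets). The control 3 reading was as low as Foxe1 in the knockouts, close to background, so the size of this difference is uncertain. Iyd differed by 2.10 (adjusted p = 0.136), Tshr by 1.75 (adjusted p = 0.167) and Duox1 by 1.11 (adjusted p = 0.216), each with all 3 knockouts above all 3 controls. The remaining members were Dio1 (0.86), Slc26a4 (0.41), Ano1 (0.35), Kcnq1 (0.30), Slc26a7 (0.25), Kcne2 (0.07), Tg (0.04) and Duoxa2 (-1.07), with adjusted p of 0.414 or more. Thyroglobulin, Tg, lay at 18.95 ± 0.30 in controls and 19.00 ± 0.25 in knockouts, close to the highest value in the table, 19.93, where differences may be compressed. As a set the list was higher than other probe sets (mean difference 0.92, median 0.38, camera adjusted p = 0.0013). Slc5a5 had the largest difference and raised the mean. The call was lost with an inter-gene correlation estimated from these arrays (adjusted p = 0.583 with an estimated correlation). Control 3 was the lowest control for several of these genes, and the list's mean difference without it was 0.58, with Slc5a5 at 3.15. Dio1 was at 0.11 without control 3 and 1.37 without control 1. Duox1 differed by 0.72 without knockout 3, Duoxa2 by -0.33 without knockout 2, and Kcnq1 by 0.093 and Ano1 by 0.23 without knockout 1. Duox2 and Duoxa1 carried no symbol among the probe sets used here.

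Of the 5 thyroid transcription factors, Foxe1 fell and Hhex rose. Hhex, a homeobox gene of the thyroid bud, went from 6.44 ± 0.48 to 8.90 ± 0.53 (SD, n = 3 each), a rise of 2.46 (SE 0.32, adjusted p = 0.0273). Its adjusted p exceeded 0.05 in all 6 fits that left out 1 array. Pax8 differed by 1.52 (adjusted p = 0.183), Nkx2-1 by 0.73 (adjusted p = 0.528) and Glis3 by 0.07 (adjusted p = 0.962). Without control 3 the difference was 0.96 for Pax8 and 0.27 for Nkx2-1, and without control 1 it was 1.18 for Nkx2-1. Adjusted over the list alone, Foxe1, Hhex and Pax8 passed. With Foxe1 among its members the list did not pass as a set (mean difference 0.12, camera adjusted p = 0.495).

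**Figure D1:**
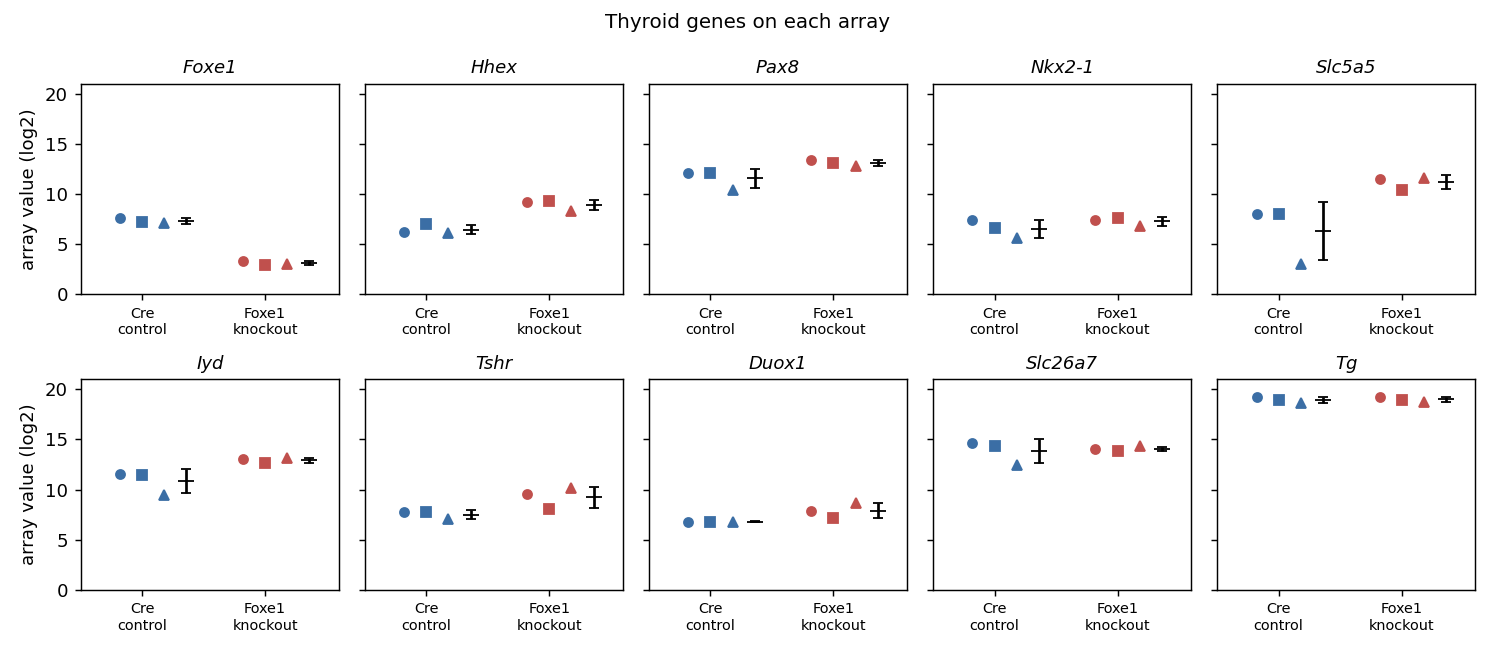
Array values (log2) of 10 thyroid genes on the 3 Cre control arrays (blue) and the 3 Foxe1 knockout arrays (red), with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean and SD. Foxe1 lies near 3 on every knockout array, Hhex and Slc5a5 lie higher in the knockout, and Slc5a5 is at 2.97 in control 3.

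In all, 13 of the 32 gene lists with at least 3 measured members passed camera with its preset correlation, 6 upward and 7 downward. None passed with an estimated correlation, where the smallest adjusted p was 0.583 and 1 list had an unadjusted p under 0.05. None passed fry either (smallest adjusted p = 0.266, with 4 lists at an unadjusted p under 0.05). The lists are described below with that limit.

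Cholesterol synthesis had the smallest camera p of the upward lists. Of 13 measured members 12 had positive differences, 7 passed when adjusted over the list alone and none over all probe sets (mean difference 0.82, camera adjusted p = 2.15e-06, 0.631 with an estimated correlation). Fdft1, which makes squalene, differed by 1.05 (adjusted p = 0.0722), Cyp51 by 1.27 (adjusted p = 0.14) and Sc5d by 0.75 (adjusted p = 0.15). Oxidative stress genes controlled by Nrf2 had 3 of 13 members past the threshold adjusted over the list alone (mean difference 0.39, camera adjusted p = 0.00915, 0.583 with an estimated correlation). They were the haem oxygenase gene Hmox1 (1.55, adjusted p = 0.0737), the cystine transporter Slc7a11 (1.52, adjusted p = 0.143) and the glutathione peroxidase Gpx2 (0.85, adjusted p = 0.101). The immediate early list, whose genes respond within minutes to stimulation or tissue handling, had 13 of 15 positive differences and no member past the threshold over the list alone (mean difference 0.54, camera adjusted p = 0.00188, 0.69 with an estimated correlation). Its mean was 0.21 without control 1 (camera adjusted p = 0.109), where Egr1 was at 1.07 and Egr3 at 0.72, and 0.89 without control 3. Egr1 differed by 1.79, Egr3 by 1.09 and Junb by 0.97, with adjusted p of 0.178 or more. Proliferation genes differed by a mean of 0.20, with 16 of 21 positive (camera adjusted p = 0.0409, 0.69 with an estimated correlation). The call was lost without control 1, control 2, knockout 1 or knockout 3 (means of 0.19, 0.092, 0.19 and 0.16, camera adjusted p of 0.0879 or more), and the mean was 0.32 without control 3. Without control 1 Bub1b was at 0.51, and without control 3 at 1.26. Bub1b, Ube2c and Kif11 differed by 0.83, 0.78 and 0.65, with adjusted p of 0.243 or more. In the squamous and basal epithelium list 9 of 11 members were positive (mean difference 0.25, camera adjusted p = 0.0409, 0.737 with an estimated correlation). Knockout 3 carried most of this: the mean was 0.011 without it (camera adjusted p = 0.353) and 0.41 without knockout 2, and the call was also lost without control 1 (0.19, adjusted p = 0.105) or control 2 (0.25, adjusted p = 0.137). Its members did not move as one. Sprr3, of the cornified envelope, differed by 1.15 and the desmosomal cadherin Dsc3 by 1.10, while the keratin Krt17 differed by -1.89 (adjusted p of 0.0907, 0.132 and 0.113). Sprr3 averaged 17.81 in the controls and 18.95 in the knockouts, so squamous transcripts were abundant in the lobes of both groups.

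Downward lists were led by muscle, airway and mitochondrial genes. All 15 skeletal muscle genes had negative differences (mean -0.69, camera adjusted p = 3.88e-06, 0.69 with an estimated correlation), and 4 passed when adjusted over the list alone, among them the calcium release channel Ryr1 (-1.31, adjusted p = 0.1), Pvalb (-1.42, adjusted p = 0.163) and Actn3 (-1.17, adjusted p = 0.181). Knockout 3 was the lowest array for muscle, and without it the mean was -0.39, with Actn3 at -0.76. All 10 airway and ciliated epithelium genes were negative too (mean -0.91, camera adjusted p = 9.87e-06, 0.583 with an estimated correlation), and 3 passed over the list alone, the airway secretory genes Bpifa1 and Muc5b (-1.48) and the ciliary gene Tppp3 (-0.70), with adjusted p of 0.15 or more over all probe sets. Bpifa1 read 19.32 ± 0.51 in the controls and 18.32 ± 0.22 in the knockouts (SD, n = 3 each), so airway transcripts were abundant in the lobes of both groups. The airway list's mean was -0.58 without control 1. All 21 oxidative phosphorylation genes were negative (mean -0.43, camera adjusted p = 3.88e-06, 0.69 with an estimated correlation), with none past the threshold over the list alone. Sdha, Sdhb and Uqcrfs1 differed by -0.76, -0.65 and -0.55 (adjusted p of 0.218 or more). Like the muscle list, this list was lowest in knockout 3 (13.24, against 13.52 and 13.61 in knockouts 1 and 2). A part played by muscle tissue in the lobes was not tested. Interferon response genes were negative in 13 of 16 (mean -0.58, camera adjusted p = 0.00104, 0.583 with an estimated correlation), with Oasl2 (-1.85, adjusted p = 0.0729) the single member past the threshold over the list alone and Irf7 (-1.22) and Usp18 (-1.11) at adjusted p of 0.18 or more. Irf7 was at -0.70 without control 2.

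The other downward lists were of stromal and immune cells, and none of their members passed over the list alone. All 16 fibroblast and matrix genes were negative (mean -0.57, camera adjusted p = 0.004, 0.737 with an estimated correlation), with Sparc at -0.98 and Pi16 at -0.93, and Fbln1 at 10.61 ± 0.93 in controls and 9.61 ± 0.55 in knockouts (SD, n = 3 each, limma adjusted p of 0.278 or more for the 3). Knockout 3 stood apart: without it the mean was -0.16 (camera adjusted p = 0.522). The mean was -0.39 without control 3 (camera adjusted p = 0.0659) and -0.90 without knockout 1. All 11 adipocyte genes were negative (mean -0.50, camera adjusted p = 0.0214, 0.69 with an estimated correlation), with Pnpla2 at -0.61, Plin1 at -0.50 and Adipoq at -0.40 (adjusted p of 0.453 or more). Control 1 carried most of this, with a mean of -0.20 without it (camera adjusted p = 0.433) and Pnpla2 at -0.34, Plin1 at -0.17 and Adipoq at -0.17, and the call was also lost without knockout 3 (-0.45, camera adjusted p = 0.0983). Macrophage and dendritic cell genes were negative in 16 of 18 (mean -0.36, camera adjusted p = 0.0128, 0.69 with an estimated correlation). Itgam differed by -1.12, Cd14 by -1.08 and Cx3cr1 by 0.45, with adjusted p of 0.148 or more. The mean was -0.17 without knockout 3 (camera adjusted p = 0.407) and -0.25 without control 3 (camera adjusted p = 0.105).

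**Figure D2:**
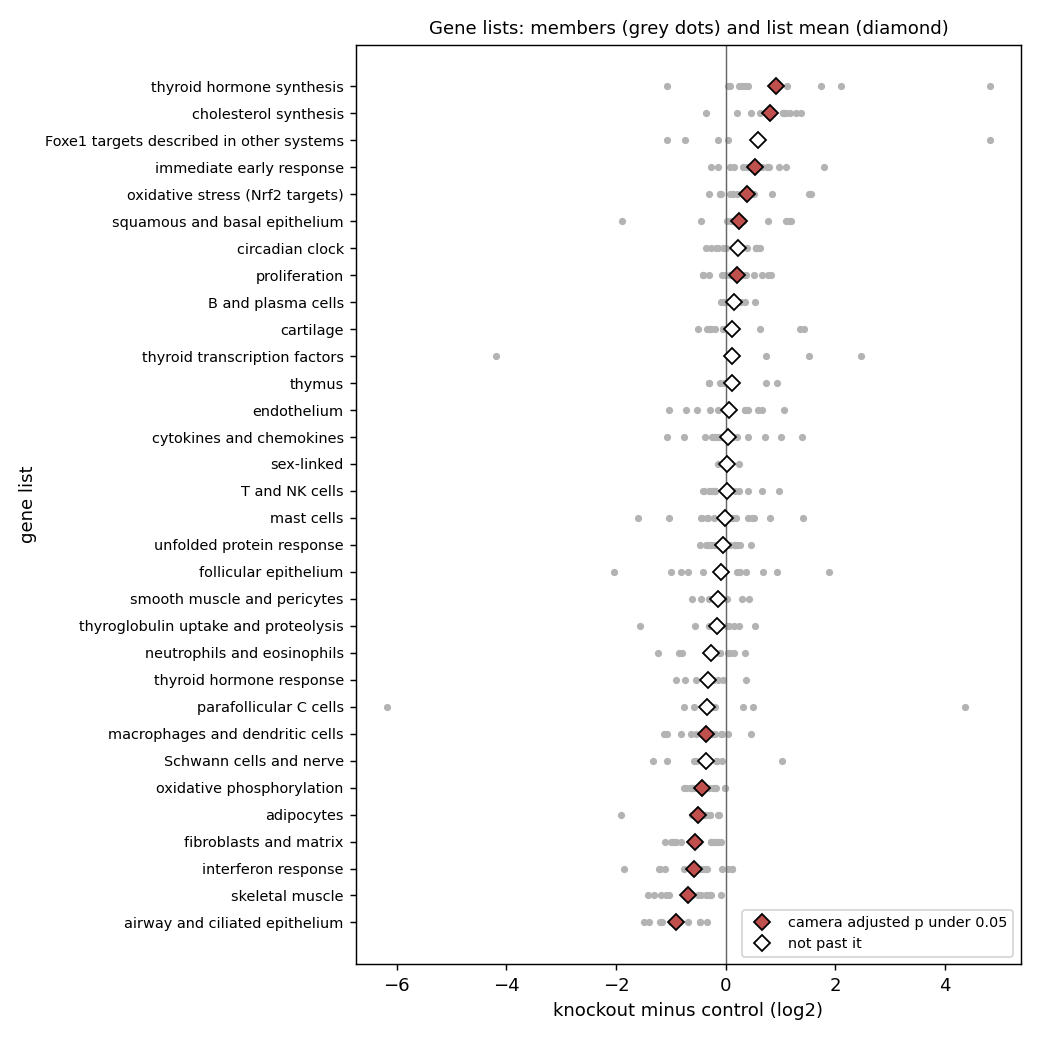
Difference between knockout and control (log2) for the members of each of 32 gene lists (grey dots) and their mean (diamonds, red where camera with its preset correlation gave an adjusted p under 0.05). The list means run from -0.91 for airway and ciliated epithelium to 0.92 for thyroid hormone synthesis.

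The mast cell list was included because the study is known to concern mast cells in these glands, and so it is not independent evidence. Its 20 measured members were split evenly, 10 positive and 10 negative (mean difference -0.02, camera adjusted p = 0.973), and none passed over all probe sets. Among probe sets above the median level the list's mean was 0.20 (camera adjusted p = 0.68). Many of the 20 read low, such as Tpsab1, Gzmb and Tpsg1 (2.71, 2.75 and 2.90 in the controls), below the lower quartile of every array, 3.49 to 3.60. Members near background can show little change, so the even split does not measure an absence of change. Adjusted over the list alone, 2 passed, both lower in the knockout: the serotonin transporter Slc6a4 (-1.04, adjusted p = 0.0653 over all probe sets) and the stem cell factor receptor Kit (-1.60, adjusted p = 0.101). The granule protease genes Cpa3 (1.42, adjusted p = 0.261) and Tpsb2 (0.81, adjusted p = 0.347) lay higher on all 3 knockout arrays than on any control. Single arrays weighed on both: Cpa3 read 8.32 in control 1 against 10.13 and 9.98 in controls 2 and 3. Tpsb2 read 7.24 in knockout 1 but 5.96 in knockout 3, next to 5.95 in control 3. At an unadjusted limma p under 0.05, 3 of the 20 members were higher and 2, Slc6a4 and Kit, lower. The 3 were Cpa3, Tpsb2 and the protease gene Mcpt9 (0.52, adjusted p = 0.317), which averaged 3.36 in the controls, near background. Of other protease genes, Mcpt4 differed by 0.41 and Mcpt1 by -0.45 (adjusted p = 0.675 and 0.558). All mast cell genes named here were chosen after their values were seen.

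In the remaining lists camera passed nothing. Its adjusted p was 0.839 for Foxe1 targets described in other systems, for thyroglobulin uptake and proteolysis, for follicular epithelium, for endothelium and for smooth muscle and pericytes. It was 0.621 for parafollicular C cells, 0.961 for T and NK cells, 0.325 for B and plasma cells, 0.688 for neutrophils and eosinophils, 0.714 for thymus, 0.787 for cartilage and 0.136 for Schwann cells and nerve. It was 0.114 for the circadian clock, 0.961 for sex-linked genes, the unfolded protein response and cytokines and chemokines, and 0.105 for the thyroid hormone response. In the C cell list Scg5 rose, as given above, while 8 of the 11 members were negative. The mean, the median and the camera direction differed in sign for Foxe1 targets, thyroglobulin uptake, mast cells, T and NK cells, cartilage, sex-linked genes and cytokines. Of these lists, follicular epithelium had 2 members higher and 3 lower when adjusted over the list alone, T and NK cells 1 higher, Foxe1 targets 1 higher, thyroglobulin uptake 1 lower, and endothelium and Schwann cells 1 each way.

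Parathyroid genes and the Y-linked genes differed between lobes of the same group. Pth, parathyroid hormone, read 18.24, 19.68 and 17.02 in the controls and 3.56, 18.61 and 10.06 in the knockouts (difference -7.57, adjusted p = 0.335), and Chga, a granin shared by parathyroid and C cells, read 15.74, 17.63 and 13.15 against 5.85, 15.16 and 6.95 (adjusted p = 0.277). Only Pth and Casr of the parathyroid list were measured, and Alas2 with 1 other gene of the red blood cell list, too few for a set test. The 3 measured Y-linked genes averaged between 8.03 and 8.30 on 4 arrays, and 3.04 in control 1 and 2.65 in knockout 3. With the parathyroid level as a covariate, chosen after these values were seen, 2 probe sets passed, 1 of them among the 75, while the median size of the 75 differences was 1.86 in place of 1.83 and their median SE 0.33 in place of 0.23. Without the 2 arrays lacking Y-linked signal 6 passed. No call among the 75 changed sign in either fit. Leaving out arrays could not change one, since each had all knockouts on one side of all controls.

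**Figure D3:**
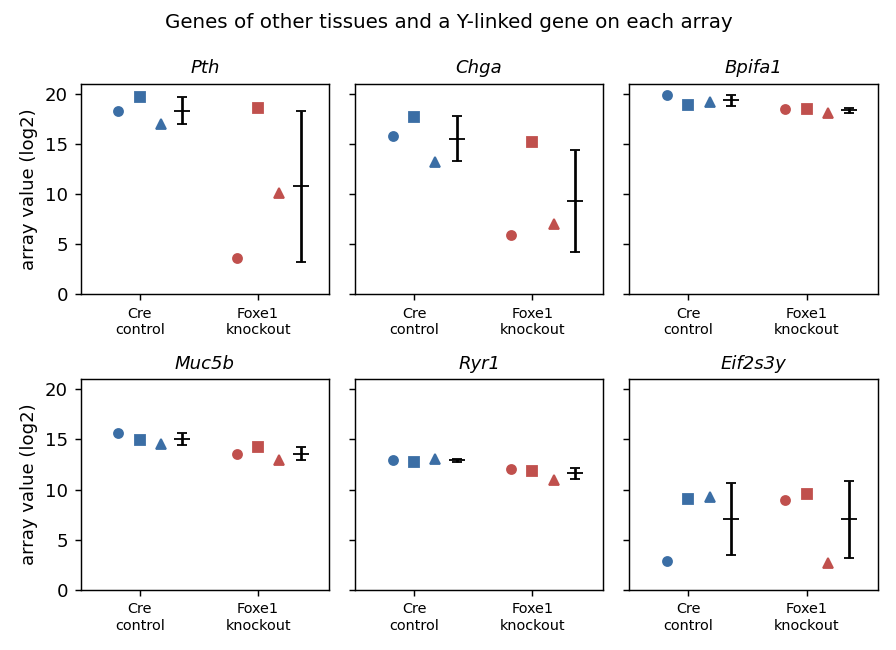
Array values (log2) of a parathyroid gene (Pth), a granin (Chga), airway genes (Bpifa1 and Muc5b), a muscle gene (Ryr1) and a Y-linked gene (Eif2s3y) on the 3 control arrays (blue) and the 3 knockout arrays (red), with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean and SD. Pth spans 3.56 to 18.61 in the knockouts, and Eif2s3y is near 3 in control 1 and knockout 3.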

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

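Foxe1 stayed lower, with log2 differences between -4.39 and -4.01, and past the threshold under the alternatives run on it except the ordinary t statistic (-4.19, adjusted p = 0.223). The filter above the median level removes it. Of the 75 calls none changed sign under any alternative. Most alternatives could not change one: leaving out arrays keeps all knockouts on one side, and other variance models, filters or the block keep the difference itself. Power was limited too: 18% of simulated changes of 1 log2 unit were recovered. That simulation drew probe sets independently and held no differences in tissue content, so it does not measure the limit these set.

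The count of probe sets past the threshold depended on the settings. It was 118 (89 higher, 29 lower) with a variance trend fitted robustly and 260 (181 higher, 79 lower) at an adjusted p under 0.1. It was 2149 (1152 higher, 997 lower) at an unadjusted p under 0.05 with a 1.5-fold change, 806 (503 higher, 303 lower) with a 2-fold change, and 0 (0 higher, 0 lower) with an ordinary t statistic and adjustment, where limma's unadjusted p under 0.05 numbered 2828. Leaving out 1 array gave 2 to 43, 1 to 30 higher and 1 to 13 lower; smaller groups are the construction of these fits. Among alternatives added after seeing the data, leaving out the 2 arrays without Y-linked signal gave 6 (4 higher, 2 lower), the parathyroid level as a covariate 2 (0 higher, 2 lower), and sex as a covariate 92, with 29 lower. In the latter, 68 of the 75 remained. The causes were not tested otherwise. Camera's 13 lists became 0 with an estimated correlation and 0 with fry, and stayed between 9 and 15 elsewhere.

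Replicate numbers did not pair the arrays: deviations of same-numbered arrays from their group means correlated at -0.009, 0.076 and 0.0172, and not every array correlated best with its own number. With the replicate number as a block, 63 probe sets passed and 38 of the 75 remained; Foxe1 differed by -4.19 (adjusted p = 0.00435) and 13 lists passed.

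The sign of a mean difference changed only for lists and genes far from any threshold, apart from the squamous and basal list, called with all arrays and at -0.051 without the 2 arrays lacking Y-linked signal; the causes were not tested. In that fit parafollicular C cells stood at 0.021, mast cells at 0.017, neutrophils and eosinophils at 0.049, smooth muscle and pericytes at 0.079, cartilage at -0.013 and the unfolded protein response at 0.072. With the parathyroid level as a covariate, parafollicular C cells stood at 0.25, thymus at -0.0067, endothelium at -0.017, smooth muscle at 0.042, the unfolded protein response at 0.11, Kcnq1 at -0.045, Ano1 at -0.017 and Tg at -0.060. Mast cells were at 0.015 after renewed quantile normalization, 0.030 after median centring, 0.0073 with array weights and 0.20 among probe sets above the median level. The unfolded protein response was at 0.0023 after median centring. Leaving out 1 array moved thyroid transcription factors between -0.23 and 0.30, mast cells between -0.047 and 0.042, T and NK cells between -0.030 and 0.068, neutrophils and eosinophils between -0.48 and 0.15, and endothelium between -0.18 and 0.42. It moved smooth muscle and pericytes between -0.32 and 0.10, cartilage between -0.21 and 0.37, sex-linked genes between -1.65 and 1.90, the unfolded protein response between -0.27 and 0.16, and cytokines and chemokines between -0.051 and 0.13. Among genes it moved Slc26a7 between -0.42 and 0.66, Tg between -0.10 and 0.20, Kcne2 between -0.02 and 0.14 and Glis3 between -0.39 and 0.46.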

Other observations

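Of the tests in this part, the comparison with other splits of the arrays was planned before its result was seen; the other tests were chosen only after the results they bear on had been seen. The test of follicular share replaced 2 earlier forms after their results were seen; those rested on genes picked for their higher values and exclude nothing. A test of mismatched probes near Foxe1, also run first, was dropped because a mismatch moves values either way.

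Families of genes with a shared symbol stem were grouped and tested after the data were examined. Of 628 families with at least 5 named members, 15 passed camera at its preset correlation and none with an estimated correlation (smallest adjusted p = 0.967). The Sprr family, whose proteins are cross-linked into the cornified envelope, had 9 of 13 members higher at an unadjusted p under 0.05 and none lower (mean difference 1.07, camera adjusted p = 2.14e-07, 0.967 with an estimated correlation). Sprr1b differed by 3.13 (7.65 ± 1.23 in controls, 10.78 ± 0.48 in knockouts, SD, n = 3 each, adjusted p = 0.0624). The late cornified envelope family Lce had 12 of 21 members higher in the same sense (mean difference 0.77, camera adjusted p = 2.42e-06, 0.967 with an estimated correlation), and Dsg, the desmogleins, 4 of 6 (mean difference 0.62, camera adjusted p = 0.0487). In the Skint family 3 of 11 members rose over all probe sets, Skint6 by 2.93, Skint3 by 1.55 and Skint1 by 1.20 (mean difference of the family 0.87, camera adjusted p = 1.07e-05, 0.967 with an estimated correlation).

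The other upward families were Rpl, of ribosomal proteins (mean difference 0.22, camera adjusted p = 0.000612), Dlg (0.77, 0.00516), Arpc (0.54, 0.0126), the carboxylesterases Ces (0.38, 0.0252) and Serpinb (0.30, 0.0481). Of the downward families, Cfap, of cilia and flagella, had 9 of 30 members lower at an unadjusted p under 0.05 and none higher (mean difference -0.48, camera adjusted p = 0.000612, 0.967 with an estimated correlation). Ndufb and Ndufa, of respiratory complex I, had mean differences of -0.40 and -0.33 (camera adjusted p = 0.00918 and 0.0487). Scgb, the secretoglobins, had 6 of 26 members lower and 1 higher (mean difference -0.70, camera adjusted p = 0.00246). The uroplakin family Upk had a mean difference of -0.99 (camera adjusted p = 0.0481), with Upk1b at -2.26 and Upk3bl at -2.04 (adjusted p = 0.163 and 0.0525), and the Asb family of -0.37 (camera adjusted p = 0.0481).

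Of these 15 families, Sprr, Lce, Skint, Rpl and Dlg passed without any single array, though the mean of Lce was 0.37 without control 1. The other 10 lost the call without 1 array or more, with camera adjusted p between 0.0513 and 0.409. Without control 1 the means of those that lost it were -0.25 for Cfap, -0.55 for Scgb, -0.31 for Ndufb, 0.48 for Arpc, -1.06 for Upk, 0.27 for Serpinb, -0.20 for Ndufa and 0.50 for Dsg. Without control 2 they were -1.05 for Upk and 0.32 for Serpinb. Without control 3 they were 0.36 for Ces, -0.85 for Upk, -0.28 for Asb and 0.65 for Dsg, and Scgb, still past the threshold, was at -1.05. Without knockout 1 they were -0.58 for Scgb, -1.08 for Upk, -0.40 for Asb, 0.29 for Serpinb, -0.36 for Ndufa and 0.65 for Dsg. Without knockout 3 they were -0.58 for Scgb, -0.29 for Ndufb, 0.49 for Arpc, 0.29 for Ces, -0.26 for Asb, 0.22 for Serpinb, -0.23 for Ndufa and 0.52 for Dsg.

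The 75 calls were set against the other ways to divide the arrays. Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many; the highest of the others gave 0. With 10 splits the share cannot be under 0.05, so the splits decide nothing about chance.

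Besides Foxe1 itself, 3 called probe sets lay among the 200 named genes nearest to Foxe1 on chromosome 4. Xpa, a nucleotide excision repair gene and the nearest named gene on one side, was higher by 2.09 (adjusted p = 0.0155); Ncbp1, the next on that side, differed by 1.20 (adjusted p = 0.122) and Trmo, the nearest on the other, by -0.18 (adjusted p = 0.754), while Gm3893 and Dnaic1 were lower by 3.22 and 1.21 on the log2 scale (adjusted p = 0.0271 and 0.0445). Elsewhere, windows of 200 neighbouring genes held a median of 0 calls and a 95th percentile of 2, and 2.62% held 3 or more, with 5 as the highest. On the rest of chromosome 4, 5 of 978 genes were called, among them Alad, Hdhd3, Skint6, Skint3 and Skint1. Over the genome, calls numbered 0.68 per 200 genes. An effect of the deletion on genes directly beside it cannot be the whole account, since 2 of the 3 lay more than 10 genes away; for Xpa it stays open, beside an effect of the missing Foxe1 protein. DNA of another strain carried along with the floxed gene stays undecided. The 3 calls, which prompted the test, exceed what 95% of windows held. Among them is Dnaic1, a gene of ciliary dynein, and the airway and ciliated list was also lower. Differing tissue in the lobes may thus have added to the count. An unadjusted limma p under 0.05 was reached by a similar share, 15% of the 200 genes against 13% elsewhere. Both groups are labelled C57BL/6J.

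Pth and Chga were lower on average in the knockout without passing the threshold. Loss of Pth in every knockout is argued against by 1 array, knockout 2, which read 18.61 and lay within the control range. Lobes that carried different amounts of parathyroid tissue may explain the spread: deviations from the group means over the 6 arrays correlated at r = 0.92 for Pth and Chga (rho = 0.943, exact permutation p = 0.0278 for both, permuted within groups, where 36 arrangements allow no smaller p). For Pth and Casr r was 0.615 (rho = 0.829, exact permutation p = 0.0278 and 0.0556), and for Casr and Chga 0.774 (rho = 0.657, exact permutation p = 0.0278 and 0.111), with 0.0278 for r in each pair after adjustment over the 3, but the lowest r lay between the bounds set for and against, which left this undecided. Without the 2 arrays farthest from the median r was 0.957, 0.972 and 0.411 for these 3 pairs in turn, so the relation of Casr and Chga rests on those arrays.

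The higher thyroid hormone synthesis genes were set against 2 technical accounts. A larger share of follicular cells in the knockout lobes would lift alike members that come from those cells alone and read above background. Slc26a4 and Kcne2 averaged 2.46 and 2.93 in the controls, and Slc5a5 read 2.97 in control 3, so these may not follow it. Ratios on the same array were taken for the 55 pairs among the 11 members other than Tg. Between the groups 7 differed (limma adjusted p between 0.0179 and 0.0416). Of these, 4 were without Slc5a5 and 1, Iyd with Slc26a7, without Slc5a5 and Duoxa2. The log2 ratio of Iyd to Slc26a7 was -2.99 ± 0.11 in controls and -1.14 ± 0.15 in knockouts (SD, n = 3 each). A larger share alone would not move that ratio if both genes come from follicular cells alone. The pairs share members, so a larger share is not excluded as part of the rise. Less thyroid signal in control 3 may account for part, since without it the list's mean difference was 0.58 in place of 0.92, between the bounds set for and against it. A change of these genes within follicular cells, with the genotype, stays open beside these accounts, as a hypothesis that values from whole lobes cannot decide.

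Alad, the called gene that held without any single array besides Foxe1, has Hdhd3 as its neighbour on chromosome 4, and Hdhd3 was also higher (3.71 ± 0.23 to 5.41 ± 0.24, SD, n = 3 each, difference 1.71, adjusted p = 0.0267). Both lie on the chromosome of Foxe1, outside the 200 named genes nearest to it, so the window test does not cover them. For these genes, DNA of another strain carried along with the floxed gene was not separated from an effect of Foxe1 loss.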
